A study of Mus musculus with 8 samples.

How the data were processed

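Gene expression was measured on 8 arrays, all named under 1 chip identifier. The 4 SKI-606 tumours lay at the first chip positions and the 4 vehicle tumours at the last, so position and group cannot be told apart. Per the labels' protocols, 8 ng of total RNA was reverse transcribed, and the drug was given at 100 mg/kg in methocellulose (0.5%) with a detergent (0.4%). Groups and replicate numbers came from the sample titles. The title of 1 vehicle sample has no number, and the number 3 given to it here only names it. The array software, its version and any genome build are not given in the sources used here.

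The deposited signal table held an average intensity per probe and array, not background-subtracted and not normalized between arrays, as its values showed. Per the file headers, it also held a detection p-value for each probe on each array. The authors deposited a second table of intensity values on a linear scale for 11434 probes, which are exactly the probes with a detection p under 0.01 on at least 1 array. Its columns shared the same quantiles, with medians between 234.2 and 234.3, and ranked each array as that array's own signals did (rank correlation 1). Its values were used only as an alternative. No other column of per-sample values was left aside.

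From the signal table, intensities were background-corrected with normexp and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (offset 16, negative controls inferred from the detection p-values), then put on the log2 scale. The 4 bacterial control probes were left out. Probes with a detection p under 0.05 on at least 4 of 8 arrays were kept, 12281 in all. SKI-606 was compared with vehicle by lmFit and eBayes, with group alone in the model, and p-values were adjusted by Benjamini-Hochberg over all kept probes. Differences are SKI-606 minus vehicle.

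The files give probe identifiers without gene names. Identifiers with a zero-padded number were named by matching that number to gene IDs of a table of RefSeq genes (GRCm38.p6), used for names only. The match rests on the data: 93.3% of 9490 such numbers met a gene ID, against 48.7% after adding 1, 25.2% after adding 1000 and 10.3% of the unpadded numbers. Of 337 probes so named as olfactory receptors 2.37% were kept, and of 88 named as ribosomal proteins 88.6%. Among kept probes, 4638 had a name, covering 4137 genes, and 7643 stayed unnamed. A gene was represented by its brightest kept probe, and 452 genes had more than 1.

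Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, for the 25 of 35 lists with at least 5 measured genes. Of 852 distinct symbols in the lists, 274 were among kept probes, so the list members counted below are the measured ones only. A list's value per tumour is the mean log2 signal of its measured genes minus the vehicle mean. Values per tumour were compared by exact two-sided permutation. The groups, the limma and gene list tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined, and the exact permutation of list values and the mean of a gene's probes were added afterwards. That rule named genes past the threshold, or else the 5 with the smallest p in each direction, 16 fixed genes, and from each list up to 4 members past the threshold over all probes or over the list alone, or else the 2 with the smallest p. Predicted genes and clones were not named, and a few genes and 1 family that the tests covered are not reported here. In 20 simulations of 12281 probes with 200 changed, the test recovered 39.7% of probes changed by 0.5 on the log2 scale, 72.2% at 1, 90.7% at 2 and 97.2% at 3, with 9.05 false calls per simulation. Simulated lists shifted by 0.75 were all called (100%), and 0.455% of unshifted lists. The simulated genes were independent of each other, unlike those of the real lists, whose estimated correlation reached 0.83 for S phase genes. That rate therefore does not carry over to the real arrays, where other splits into 4 and 4 still called 1 to 11 lists.

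Alternatives covered background correction, normalization, offset, the filter on dim probes, the variance model, array weights, the replicate number as a block, the threshold, the set test and each array left out in turn. Vehicle replicates 1 and 3 were the closest pair of arrays (r = 0.992 across probes, which are not independent replicates). They differed over 2-fold for 48 probes and were kept as separate samples. Figures were drawn with matplotlib 3.10.9.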

Results

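RNA of mammary tumours from female MMTV-PyVmT mice, a transgenic line in which the polyoma middle T antigen drives mammary tumours, was hybridised to Illumina expression arrays. SKI-606 (bosutinib), an inhibitor of the Src and Abl kinases, had been given by gavage at 100 mg/kg to the mice of 4 tumours, and the other 4 tumours came from the vehicle group. The series asks whether the drug shifts these tumours towards a differentiated state. Each array carried 24611 probes, of which 11837 to 12578 were detected per array, at a mean signal between 300.3 and 419.6. Detected probes numbered 12111 ± 295.8 in the SKI-606 group and 12242 ± 256.5 in the vehicle group (mean ± SD, n = 4 each; exact permutation p = 0.457, two-sided). The 18S rRNA probe read 6575 ± 2613 in SKI-606 tumours and 10840 ± 2237 in vehicle tumours (exact permutation p = 0.0857, two-sided, where 0.0286 was the smallest p possible). The source name of SKI-606 replicate 2 describes human islet cells, against its other labels, and the array was kept in the group of its title. The labels speak of RNA from each mouse without stating that every array is a separate animal, so p-values measure the spread between these samples. The number of arrays limits the precision of every value below.

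In the comparison of SKI-606 with vehicle tumours, the casein genes Csn2 and Csn1s1 were higher with the drug and the oxygen sensor Egln3 was lower, but no named gene passed the threshold over all probes. Lists of endothelial and of fibroblast and matrix genes were higher at a preset correlation between genes, but passed neither with an estimated correlation (adjusted p = 0.522 for each) nor with fry (adjusted p = 0.134 and 0.168). Csn2, which encodes beta-casein, had a normalized log2 signal of 14.03 ± 0.07 in SKI-606 tumours and 11.40 ± 1.53 in vehicle tumours (SD, n = 4), a 6.17-fold difference with a 95% interval of 2.03 to 18.7. The SKI-606 values lay near the brightest probe of every array (14.26), so a ceiling there would make this fold too small and its interval unreliable. Egln3, the prolyl hydroxylase that marks HIF for degradation, was 9.05 ± 0.56 against 10.94 ± 0.22, 3.71-fold lower with the drug, and its 4 SKI-606 values lay below all 4 vehicle values. The only probe past the adjusted threshold, scl15911.2_36-S, had no gene name and rose by 0.72 ± 0.06 (SE) on the log2 scale, higher in 4 of 4 SKI-606 tumours (limma adjusted p = 0.0384). Though detected on every array, it was dim, at 6.93 ± 0.09 in SKI-606 and 6.21 ± 0.04 in vehicle tumours (SD). No probe passed with a neqc offset of 50 or with an intensity trend and robust prior.

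Of 12281 probes tested with limma, 1 was higher and 0 were lower at an adjusted p under 0.05, and 30 passed at 0.1, of which 14 were higher and 16 lower. At an unadjusted p under 0.05 there were 2004 probes, 742 higher and 1262 lower, where 614.1 were expected by chance. The 2 groups did not overlap for 1373 probes (11.2%), where chance gives 2.86%. The count at 0.05 was 0 without SKI-606 replicate 3 and without each vehicle replicate, and was 7 without SKI-606 replicate 1 and 13 without SKI-606 replicate 2. With array weights, which gave SKI-606 replicate 3 the lowest weight (0.390), 185 probes passed.

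The 5 named genes with the smallest p in each direction missed the threshold, with adjusted p between 0.0987 and 0.113, and none of their SKI-606 values overlapped the vehicle values. Higher with the drug were Hsd11b1, which regenerates active glucocorticoid, by 1.33 ± 0.23 (log2 difference ± SE), and Sned1, a secreted matrix protein, by 1.11 ± 0.17. Pmp22, a myelin and membrane protein, was higher by 0.76 ± 0.13, Gas2l1 by 0.40 ± 0.06 and Fam13c by 0.31 ± 0.05. On the lower side stood Egln3 at -1.89 ± 0.27, the glucose transporter Slc5a9 at -0.93 ± 0.13 and the Mediator subunit Med30 at -0.68 ± 0.10. Ciao2b, of cytosolic iron-sulfur assembly, was at -0.56 ± 0.08 and the small GTPase Arf5 at -0.55 ± 0.08.

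Among the genes fixed beforehand, only Csn2 had non-overlapping groups, with an adjusted p of 0.161. The kappa-casein gene Csn3 read 13.95 ± 0.13 in SKI-606 and 13.80 ± 0.18 in vehicle tumours (adjusted p = 0.559), close to the brightest probe of the array at 14.26, as was Csn2 under the drug. The luminal keratin Krt8 read 12.98 ± 0.34 against 13.07 ± 0.12 (adjusted p = 0.847) and its partner Krt18 12.17 ± 0.61 against 12.18 ± 0.27 (adjusted p = 0.991). Cyclin D1, Ccnd1, read 10.77 ± 1.11 against 11.74 ± 0.52 (adjusted p = 0.448), and its other 2 probes were lower by 1.04 and 0.61 on the log2 scale. SKI-606 replicate 1 was the lowest array for all 3 probes, and the Ccnd1 difference of -0.97 was -0.48 without it and -1.37 without SKI-606 replicate 2. The proliferation marker Mki67 was at 6.63 in SKI-606 replicate 3 and between 9.38 and 9.96 in the other 7 tumours, so its difference of -0.59 ± 0.72 came from that tumour (adjusted p = 0.75). The probes of Src and Abl1, which encode targets of the drug, were not detected on enough arrays to be tested, and Wap, Lalba, Krt5, Krt14, Cdh1, Vim, Top2a and Ctnnb1 had no probe named here.

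**Figure D1:**
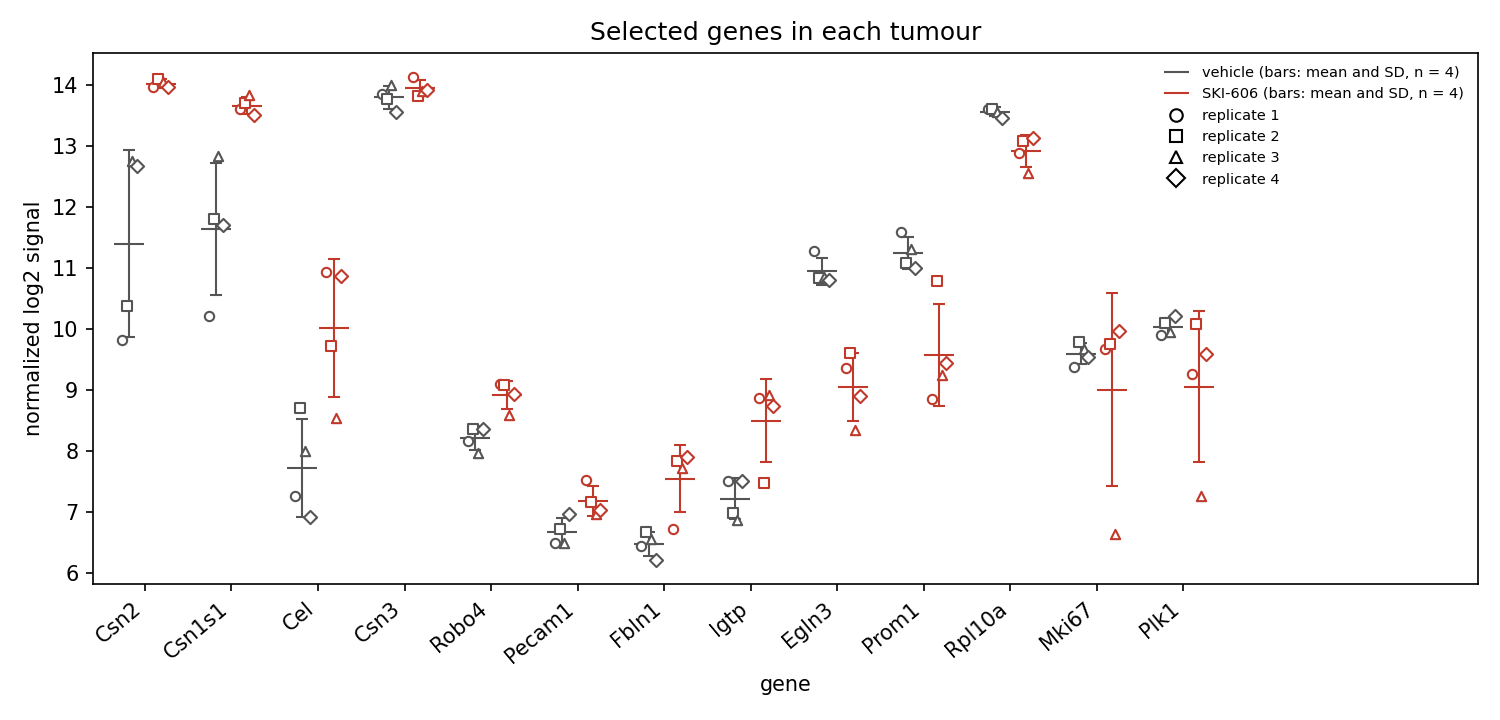
Normalized log2 signal (vertical axis) of 13 genes in each of the 8 tumours, vehicle in grey and SKI-606 in red; symbols mark the replicate, and bars give the mean and SD of 4 tumours. Csn2 lay between 13.97 and 14.11 in SKI-606 tumours and between 9.81 and 12.75 in vehicle tumours, and Mki67 was low in SKI-606 replicate 3 alone.

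Of the gene lists fixed beforehand, the endothelial, milk, fibroblast, interferon and lysosome lists rose in SKI-606 tumours, and the ribosomal protein, S phase, mitosis, cholesterol and respiratory chain lists fell. These were 10 of 25 lists tested with camera at a preset correlation of 0.01. No list passed with an estimated correlation (smallest adjusted p = 0.522 with an estimated correlation) or with fry (smallest adjusted p = 0.134), where 2 and 4 lists had an unadjusted p under 0.05. In an exact permutation of each list's mean per tumour, 4 lists reached the smallest possible p of 0.0286, which was 0.179 after adjustment. No list member passed over all probes. The 5 lists that fell did not pass when arrays were scaled to the same median (adjusted p between 0.0514 and 0.136). Their medians there, from -0.20 for ribosomal proteins to -0.97 for mitosis genes, lay further below 0 than in the main setting, with the median of all probes at -0.12.

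The milk list rose, with all 7 measured members higher and a mean per tumour of 1.15 ± 0.16 above the vehicle mean (SD, n = 4; vehicle 0 ± 0.42). The median difference of its members was smaller, at 0.43. Its camera adjusted p was 2.33e-04, and the adjusted p = 0.522 with an estimated correlation. Adjusted over the list alone, 3 members rose and 4 did not pass, with 0 passing over all probes. Csn2 rose by 2.62 ± 0.69 (log2, SE), Cel, a bile-salt-activated lipase of milk, by 2.30 ± 0.62, and the alpha-casein gene Csn1s1 by 2.03 ± 0.49, a 4.07-fold difference. The vehicle tumours differed widely in these genes, with Csn1s1 between 10.22 and 12.84. In SKI-606 tumours Csn1s1 lay between 13.52 and 13.84, near the brightest probe (14.26), so a ceiling may make its fold too small as well. Adipocyte markers, measured as signs of fat pad in the tumour piece, had a median difference of 0.94 and did not pass (adjusted p = 0.0903, and adjusted p = 0.635 with an estimated correlation), with means per tumour of 1.67 and 1.43 in SKI-606 replicates 1 and 4 and -0.16 in replicate 2. Within that list Lpl differed by 1.74 ± 0.72 and Pnpla2 by 0.55 ± 0.27, and 0 of 6 passed adjusted over the list alone or over all probes. The adipocyte list passed without SKI-606 replicate 2 (adjusted p = 0.0147, and adjusted p = 0.480 with an estimated correlation) and without vehicle replicate 4 (adjusted p = 0.0464, and adjusted p = 0.740 with an estimated correlation). With 1 array left out, the adipocyte median ran from 0.59 to 1.37.

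Endothelial markers rose (camera adjusted p = 4.53e-05, and adjusted p = 0.522 with an estimated correlation). All 7 measured members, of 22 listed, were higher, and each SKI-606 tumour lay above every vehicle tumour in the list mean. Adjusted over the list alone, 5 of 7 rose, and 0 over all probes. Robo4, a guidance receptor of endothelium, rose by 0.71 ± 0.14, the matrix protein Mmrn2 by 0.60 ± 0.14, the sialomucin Emcn by 0.55 ± 0.16 and the adhesion molecule Pecam1 by 0.51 ± 0.16 on the log2 scale (SE). Fibroblast and matrix genes rose too, 9 of 10 being higher (camera adjusted p = 2.79e-04, and adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 3 rose and 0 over all probes: Fbln1 (fibulin) by 1.08 ± 0.27 and the collagen VI chains Col6a3 by 0.58 ± 0.14 and Col6a1 by 0.44 ± 0.10. Among mesenchymal transition genes the list did not pass (adjusted p = 0.149), and adjusted over the list alone the transcription factors Zeb2 and Zeb1 rose by 0.51 ± 0.12 and 0.45 ± 0.14, with 0 of 5 over all probes.

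The interferon list rose (camera adjusted p = 0.00353, and adjusted p = 0.635 with an estimated correlation), 9 of 10 members being higher, while 0 passed adjusted over the list alone or over all probes. Igtp, an interferon-induced GTPase, differed by 1.28 ± 0.35, and the list mean of SKI-606 replicate 2, at -0.04, lay within the vehicle range. Lysosome genes rose as a list (camera adjusted p = 0.0208, and adjusted p = 0.635 with an estimated correlation), with 10 of 10 members higher and 0 past the threshold adjusted over the list alone or over all probes. The protease gene Ctsb differed by 0.32 ± 0.09 and the proton pump subunit Atp6v0d1 by 0.29 ± 0.16, and without SKI-606 replicate 1 the lysosome call was lost and its median fell from 0.29 to 0.14.

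Ribosomal protein genes fell by a small amount, with a median of -0.09 on the log2 scale and 20 of 28 members lower (camera adjusted p = 0.00484, and adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone, 2 members fell, Rpl10a by 0.65 ± 0.13 and Rplp0 by 0.56 ± 0.12, and 0 over all probes. The median was -0.15 without vehicle replicate 4 and -0.02 with cyclic loess, where the call was kept, and -0.03 with the replicate block, where it was lost. The list mean of vehicle replicate 4, at -0.25, lay below those of SKI-606 replicates 1, 2 and 4 (-0.13, -0.05 and -0.04). By exact permutation the list means gave a two-sided p of 0.257.

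Mitosis genes fell as a list, with a median of -0.73 and 12 of 12 members lower (camera adjusted p = 0.0208, and adjusted p = 0.712 with an estimated correlation), and S phase genes with a median of -0.40 and 11 of 11 lower (adjusted p = 0.0208, and adjusted p = 0.712 with an estimated correlation). The list means per tumour were uneven: for mitosis genes -2.23 in SKI-606 replicate 3, -0.34 in replicate 1, -0.10 in replicate 4 and 0.13 in replicate 2. For S phase genes they were -1.25 and -1.01 in SKI-606 replicates 3 and 1, and 0.20 and 0.07 in replicates 2 and 4. Adjusted over the list alone, 0 members passed in either list, nor over all probes. The mitotic kinase gene Plk1 differed by -0.99 ± 0.56, Cdca8 by -0.32 ± 0.18, the ribonucleotide reductase gene Rrm2 by -1.10 ± 0.59 and the clamp loader gene Rfc3 by -0.65 ± 0.19. Without SKI-606 replicate 3 both calls were lost and the medians shrank to -0.04 for mitosis and -0.19 for S phase genes. Both calls were also lost without vehicle replicate 2, with medians of -0.66 and -0.41, and the S phase call without SKI-606 replicate 1, with a median of -0.35.

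Cholesterol synthesis genes fell as a list, 11 of 13 being lower (camera adjusted p = 0.0296, and adjusted p = 0.712 with an estimated correlation), and respiratory chain genes also fell, 13 of 16 being lower (adjusted p = 0.0417, and adjusted p = 0.712 with an estimated correlation). No member of either list passed adjusted over the list alone or over all probes. In SKI-606 replicate 1 the list means were 0.048 and 0.085, above the highest vehicle tumours at 0.047 and 0.022. By exact permutation the list means gave a two-sided p of 0.257 and 0.286. Hmgcs1, an early enzyme of sterol synthesis, differed by -0.54 ± 0.24, and Atp5c1 of ATP synthase and Sdhc of complex II by -0.36 ± 0.12 and -0.31 ± 0.12. The cholesterol call, at a median of -0.26, was lost without SKI-606 replicate 3 (median -0.07), without vehicle replicate 2 (-0.15) and without SKI-606 replicate 4 (-0.23). The respiratory chain call, at a median of -0.17, was lost without SKI-606 replicate 3 (median -0.06), and with medians between -0.17 and -0.15 without SKI-606 replicate 2 or vehicle replicates 2, 3 or 4, and the median was -0.26 without SKI-606 replicate 1.

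**Figure D2:**
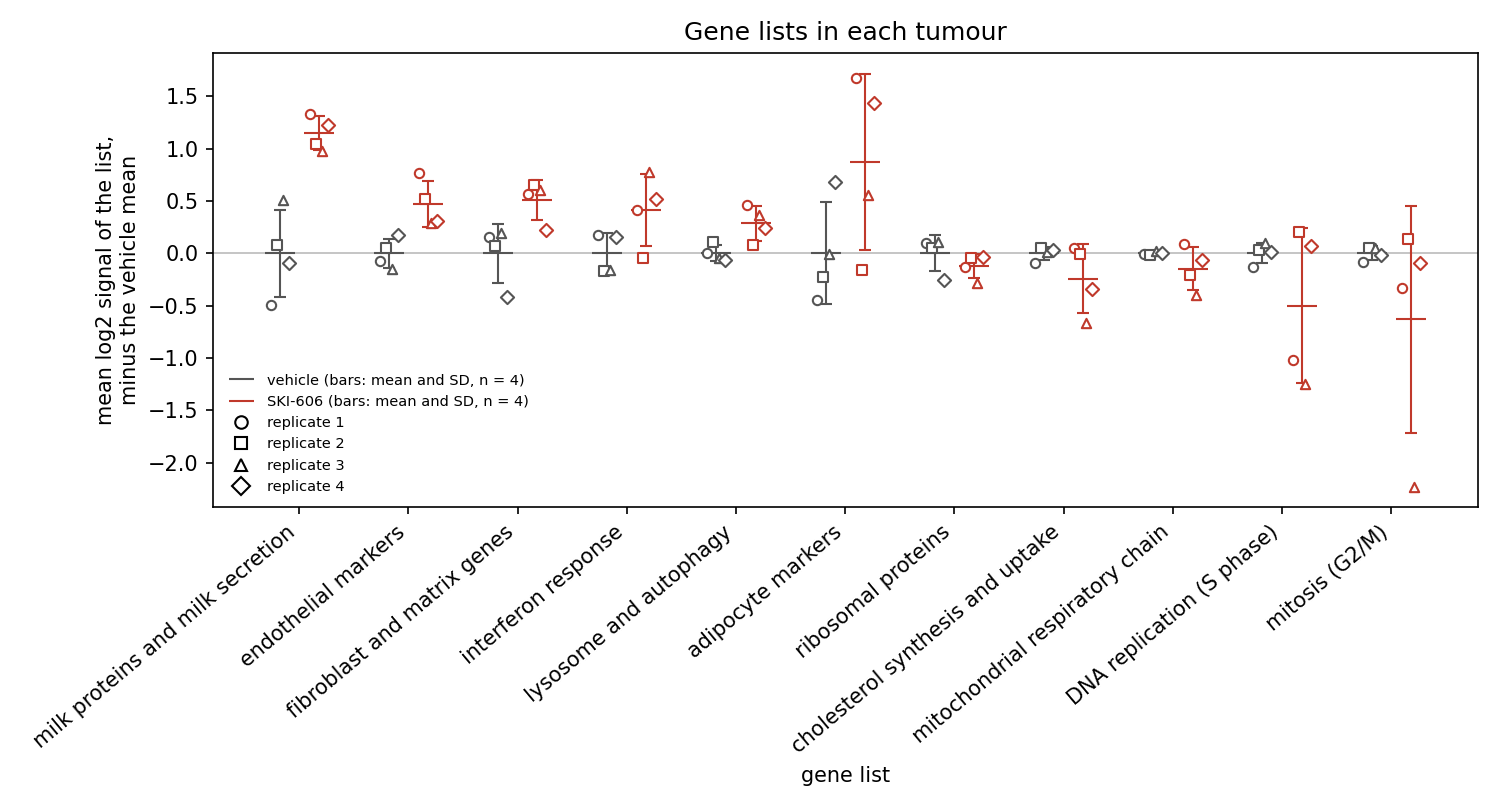
Mean log2 signal of each gene list minus its vehicle mean (vertical axis) in each of the 8 tumours, for 11 lists; grey is vehicle, red is SKI-606, symbols mark the replicate, and bars give the mean and SD of 4 tumours. The milk means of the SKI-606 tumours lay between 0.98 and 1.33, above every vehicle tumour, while the mitosis mean was -2.23 in SKI-606 replicate 3 and between -0.34 and 0.13 in the other SKI-606 tumours.

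Markers of epithelial state other than milk genes did not pass as lists. Of 10 luminal markers, 5 were higher and 5 lower (camera adjusted p = 0.896), and adjusted over the list alone only the prominin gene Prom1 fell, by 1.67 ± 0.40 or 3.18-fold, with 0 over all probes. Of 7 basal markers, the integrin gene Itgb4 rose by 0.31 ± 0.08 adjusted over the list alone, with 0 over all probes and an adjusted list p of 0.181. Epithelial junction genes had 5 higher and 5 lower (adjusted p = 0.736), with F11r at 0.28 ± 0.19 and Marveld3 at 0.26 ± 0.18. Of the focal adhesion and Src family list, 5 of 10 were lower (adjusted p = 0.824), with Zyx at -0.26 ± 0.07 and Cttn at -0.28 ± 0.10, and 0 passed adjusted over the list alone or over all probes.

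In metabolism and signalling, glycolysis and hypoxia genes did not pass as a list (camera adjusted p = 0.221), yet all 4 SKI-606 list means lay below every vehicle mean (-0.27 ± 0.08 against 0 ± 0.12, SD, n = 4; exact permutation p = 0.0286, adjusted 0.179). Adjusted over the list alone, only Egln3 fell, by 1.89 ± 0.27, with 0 over all probes. Of the 11 measured members 7 were lower and 4 higher, with a median of -0.24. Egln3 enters these list means, and the list without it was not tested. Among fatty acid synthesis genes (adjusted p = 0.295), 7 of 9 were higher, with a median of 0.37, while the elongase gene Elovl6 fell by 0.75 ± 0.18 adjusted over the list alone, with 0 over all probes. The fatty acid list mean was 1.07 in SKI-606 replicate 1 and between -0.02 and 0.14 in the other SKI-606 tumours. With 1 array left out, the fatty acid median ran from 0.041 to 0.55. In the lists below, 0 members passed adjusted over the list alone or over all probes. For Wnt genes (adjusted p = 0.789) Lgr6 differed by -0.66 ± 0.20 and Tcf7l2 by 0.47 ± 0.17, and for TGF-beta genes (adjusted p = 0.581) Tgfb3 by 0.62 ± 0.21 and Tgfbr1 by 0.19 ± 0.08. For immediate early genes (adjusted p = 0.435) Klf2 differed by 0.64 ± 0.24 and Junb by 0.24 ± 0.30, and for heat shock genes (adjusted p = 0.804) Hspa8 by 0.14 ± 0.08 and Hspb1 by -0.67 ± 0.40. Apoptosis genes (adjusted p = 0.585) had Casp8 at 0.25 ± 0.10, and cell cycle inhibitors (adjusted p = 0.656) had Btg1 at -0.79 ± 0.25 and Mxd4 at -0.08 ± 0.19. Macrophage markers (adjusted p = 0.564) had Csf1r at 0.35 ± 0.12 and C1qb at -0.27 ± 0.15, and fell as a list without SKI-606 replicate 2 (adjusted p = 0.0304, and adjusted p = 0.480 with an estimated correlation). The immunoglobulin kappa constant probe read 8.35 ± 1.15 in SKI-606 and 7.01 ± 0.85 in vehicle tumours, with an adjusted p of 0.36. Lists of Notch, ErbB, unfolded protein, T and NK cell, B cell, neutrophil, muscle, keratinocyte, erythroid and pancreatic islet genes had under 5 measured members and were not tested, with 0 measured islet genes.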

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

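The tests of the 3 patterns weighed here were chosen after the results were seen, and the other splits of the arrays before. Of the 35 ways to part the 8 arrays 4 and 4, only 1, the real one, gave as many probes past the adjusted threshold (1 probe, against at most 0). A count of 1 that was 0 without SKI-606 replicate 3 or any vehicle replicate is too small to say more. For the 2004 probes at an unadjusted p under 0.05, only 1 split, the real one, came that high and the highest other gave 1464. By chance the real split would come first in 1 of 35 cases, so chance is argued against for that count but not excluded. Chip position, which cannot be told apart from group, could give the same rank. For the gene lists, 3 of 35 splits gave as many as the real 10, with 11 as the highest other, so chance cannot be excluded for the number of lists.

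Milk genes were higher in SKI-606 tumours, by 1.15 in the list mean and 0.43 in the list median, with Csn2, Cel and Csn1s1 carrying most of the mean. Scaling between arrays is argued against, since the lowest bound of the interval over 5 normalizations was 0.37, and 0.083 for Cel and Muc15, the members away from a ceiling of the signal. Muc15 was dim, at 6.21 against 6.09, and was detected on 3 of 4 vehicle arrays. The second bound therefore rests mainly on Cel, whose groups overlapped. Fat pad in the pieces stays open: with the adipocyte mean per tumour as a covariate the difference was 1.00 ± 0.28 (SE, 95% interval 0.27 to 1.72) over all members, but -0.20 to 2.12 for Cel and Muc15. A linear drift along the chip would need -0.29 per position: within groups the change was 0.063 (95% interval -0.21 to 0.34), but a ceiling in the SKI-606 arrays would flatten it, and the 4 vehicle arrays alone allowed -0.69 to 1.01. An effect of the drug may be the cause, as a hypothesis, but normal gland in the pieces and drift or other effects of chip position remain open, the last since position and group cannot be told apart.

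Mitosis genes were low in SKI-606 replicate 3, where all 12 had their lowest value of the 8 arrays. In signals before normalization their median lay -2.51 from the other 3 SKI-606 arrays, while genes matched on signal lay at 0.073 and the lowest of 10000 random lists of them at -0.39, which argues against a weaker signal of the whole array. After normalization the median of 10 luminal markers in the same array lay at 0.16 and that of the mitosis genes at -2.68 (exact permutation over genes p = 1.95e-04 for the difference). That p treats co-expressed genes of 1 tumour as independent (estimated correlation 0.81 in the mitosis list) and does not measure the spread between tumours. Single luminal markers went both ways: Krt18, at 13.1, lay above the other 3 SKI-606 arrays and Krt19, at 8.84, below them. The median of these 10 markers did not fall with the mitosis genes. That argues against a loss of tumour epithelium only as far as the median tracks it. RNA damage that spares most transcripts was not tested and stays open beside a lower proliferation in that tumour, which may remain as a hypothesis. Whether the drug caused it is open: in the other SKI-606 tumours the mitosis means lay between -0.34 and 0.13, while the S phase mean was also low in replicate 1, at -1.01.

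SKI-606 replicate 2 lay closest to vehicle replicate 2 (r = 0.984 across probes), as SKI-606 replicate 4 did to vehicle replicate 3 (r = 0.983). Human islet RNA, which its source name could mean, is argued against by 12467 detected probes, within the 11837 to 12578 of the other arrays. Of 6 probes of islet genes 0 were detected on it. That cannot decide, since the first test presumes that mouse probes miss human RNA. A shared litter or day of these 2 arrays stays open, since their deviations correlated at 0.63, while 0.004 and -0.02 for the pairs numbered 1 and 4 show only that the numbers do not pair the samples in general. A vehicle tumour under the wrong label cannot be told apart from a weak responder. On the drug difference built without it (0 vehicle, 1 SKI-606) SKI-606 replicate 2 projected at 0.33, above the highest vehicle array at 0.23. It lay just under the 95% prediction bound of 0.335 for 1 more vehicle array. A looser bound set first, the highest vehicle array plus 1 SD (0.272), would have placed it outside. Both bounds are approximate, since the vehicle arrays were projected on differences that held SKI-606 replicate 2 among the SKI-606 tumours. Those differences rested on 1504 to 1696 probes, against 2360 for SKI-606 replicate 2. Of the 10 lists that passed, SKI-606 replicate 2 lay beyond every vehicle tumour in the drug's direction in 4 (milk, endothelial, fibroblast and respiratory chain). It lay within their range in 4 (interferon, lysosome, ribosomal and cholesterol) and beyond that range in the opposite direction in 2 (S phase and mitosis). These lists and directions came from a fit that held this array among the SKI-606 tumours, so these places are no test of its label. Without it the respiratory chain call was lost (camera adjusted p = 0.187). Exchanging SKI-606 replicate 2 with 1 vehicle tumour left 512 to 1464 probes at an unadjusted p under 0.05, against 2004, the 1464 being the highest of the other splits.

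In 14 of 184 groups of 4 (7.61%), 1 sample lay far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. Single values far from their group were Egln3 at 11.27 in vehicle replicate 1, Arf5 at 8.71, Krt8 at 12.89 and Marveld3 at 9.69 in vehicle replicate 2, and Mki67 at 6.63 in SKI-606 replicate 3. Others were Fbln1 at 6.72 in SKI-606 replicate 1, Igtp at 7.47 and C1qb at 9.92 in SKI-606 replicate 2, and Casp8 at 8.61 in SKI-606 replicate 4. Among list means, vehicle replicate 4 stood at -0.12 for epithelial junctions and -0.66 for heat shock. Fatty acid synthesis stood at -0.18 in vehicle replicate 1 and at 1.07 in SKI-606 replicate 1, and Wnt genes at 0.28 in SKI-606 replicate 2.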

How the results depend on the processing

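The set test by exact permutation and the mean of a gene's probes were chosen after the data were seen. The count of probes was 1 in the main setting and 1 with cyclic loess, without background correction, in the authors' table, without a filter and with detection on at least 1 array. It was 0 with median scaling, offset 50, detection on all 8 arrays, an intensity trend with robust prior, a 2-fold minimum and distinct genes, 30 at an adjusted p under 0.1 and 185 with array weights (92 higher, 93 lower). Unadjusted p under 0.05 gave 1436 to 2636 probes over these settings. The lowest was 1436 of 8397 tested, with detection on all 8 arrays, and the highest 2636 of 24607, without a filter. The main setting gave 2004 of 12281, and the replicate number as a block 1431 of 12281. These counts depend on the number of probes tested, and other causes of each change were not tested. Leaving out 1 array gave 0 to 13 probes and 6 to 11 lists, 6 without SKI-606 replicate 3 and 6 without vehicle replicate 2. The count of lists was 10, then 6 with median scaling (6 up, 0 down, where the main split was 5 and 5), and 0 with an estimated correlation, fry and exact permutation, whose smallest p can pass only where most lists reach it. Median scaling moved the median of all probes to -0.12, so values below for it are read against that shift. The milk, endothelial, fibroblast and interferon calls were kept in 12 other settings and in all 8 fits with 1 array left out. Of those 12 settings the ribosomal and lysosome calls were kept in 10, S phase and cholesterol in 9, mitosis in 7 and respiratory chain in 5. The adipocyte list passed with median scaling, detection on all 8 arrays and array weights and glycolysis with the replicate block, at the preset correlation (adjusted p between 0.482 and 0.758 with an estimated correlation). The replicate number was tried as a replicate block on the 6 arrays that share one, where 0 probes and 6 lists passed; the correlations of the pairs' deviations were 0.004, 0.63 and -0.02, and not every sample correlated best with its own number. Depth is not counted on arrays, and signal near background limits what dim probes can show.

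Signs turned for values that had not passed. Under median scaling, Junb was -0.026, Tgfbr1 -0.025 and Casp8 -0.029, and list medians were -0.15 for luminal, -0.0015 for basal, -0.27 for cell cycle inhibitors, -0.025 for TGF-beta, -0.051 for immediate early and -0.091 for heat shock genes. With cyclic loess, Krt18 was 0.034, junctions 0.030 and the Src family list 0.033, and without background correction the last was 0.028. With the replicate block, Mki67 was 0.23, luminal -0.10, junctions 3.27e-04, cell cycle inhibitors -0.13, apoptosis 1.59e-04 and Src family 0.0073. With array weights, basal was -0.038, junctions 0.045, mesenchymal -0.039, cell cycle inhibitors -0.13 and immediate early genes -0.012. With detection on all 8 arrays, junctions were 0.042, apoptosis 0.10 and Wnt 0.0081, in the authors' table apoptosis was 0.063, without a filter cell cycle inhibitors were -0.0065, and with the mean of a gene's probes junctions were 0.0011. Leaving out 1 array, values ran from -0.19 to 0.073 for Krt8, -0.30 to 0.17 for Krt18, -0.91 to 0.20 for Mki67, -0.010 to 0.43 for Junb and -0.24 to 0.025 for Mxd4. List medians ran from -0.11 to 0.12 for luminal, -0.010 to 0.22 for basal, -0.029 to 0.047 for junctions, -0.19 to 0.11 for cell cycle inhibitors, -0.012 to 0.048 for apoptosis, -0.036 to 0.034 for Src family, -0.084 to 0.032 for Wnt, -0.044 to 0.10 for TGF-beta, -0.0053 to 0.24 for immediate early and -0.25 to 0.19 for heat shock genes.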

Other observations

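Gene families tested only after the values were seen, 12 in all, gave 3 with an adjusted camera p under 0.05. Their members were taken by patterns in the gene symbol, so a family can hold genes that its name does not describe. Examples are Ndufaf4 among complex I subunits and Eif4ebp1 among translation initiation factors. Mitochondrial ribosomal proteins fell, with 29 of 33 members lower and a median of -0.21 on the log2 scale (adjusted p = 1.2e-06, and adjusted p = 0.484 with an estimated correlation). Adjusted over the family alone, 4 fell, among them Mrpl47 by 0.50 ± 0.09 and Mrps5 by 0.48 ± 0.09 (SE). The cytosolic ribosomal list had a median of -0.09, and the difference between both groups of genes was not tested. The median of the mitochondrial family was between -0.43 and -0.14 over 5 normalizations.

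The Gbp, Irg, Ifi and Ifit families of interferon-induced genes rose, 8 of 10 being higher with a median of 0.61 (adjusted p = 0.00142, and adjusted p = 0.484 with an estimated correlation). Adjusted over the family alone, 4 rose, with Ifi205 at 1.16 ± 0.28, Igtp at 1.28 ± 0.35, Irgm2 at 1.10 ± 0.30 and Ifi47 at 1.05 ± 0.32, and Igtp also stands in the interferon list. H2 genes of the major histocompatibility complex rose as a family, 12 of 13 being higher with a median of 0.30 (adjusted p = 0.00731, and adjusted p = 0.484 with an estimated correlation), while 0 passed adjusted over the family alone. The H2 median was 0.03 when arrays were scaled to the same median, which itself moved the median of all probes to -0.12. Proteasome subunits, complex I subunits, mitochondrial import, translation initiation factors, solute carriers, collagens, keratins and tRNA synthetases did not pass, with adjusted p between 0.182 and 0.647.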
